A study of Rattus norvegicus with 16 samples.

How the data were processed

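Liver RNA of 16 rats in 4 groups of 4 was measured on Affymetrix RG-230 PM array strips. Per the labels' protocols, pieces of liver lay in RNAlater for several days in the cold, total RNA was isolated with RNeasy columns, and biotin-labelled antisense RNA was made with the 3'IVT Express kit, which primes at the poly(A) end. The submitters' processing notes name RMA and Affymetrix Expression Console, with versions not given in the sources used here. The authors deposited log2 expression values, 1 per probe set and array, with 2 decimals. RMA corrects background, applies quantile normalization and combines the probes of a set, so the arrays arrive with nearly equal distributions and a shift of all transcripts in one group would not show. Detection calls and probe-level signals were not used here. Strip position and scan date are not given in the labels, so a batch effect of either cannot be checked. The time of day of sampling is not given either.

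All computations started from these log2 values. The table had 31139 probe sets, of which 97 were array controls and were left out of the tests. A probe set was kept when it exceeded the 30th percentile of all values (3.68 log2) on at least 4 arrays, which kept 22634 and dropped 8408. As a gauge of background, antigenomic control sets with 3 to 24 G or C bases lay at or below 3.44, and the set with 25 lay at 4.34 to 5.13. Gene names came from the platform's annotation, in which 19068 probe sets had 1 symbol, 573 had several and were not named, and 11407 were not listed. Of those with 1 symbol, 18989 matched a current rat gene (GRCr8 RefSeq table) through the Entrez identifier, 79 kept the array's symbol and 0 changed. A gene was represented by its probe set with the highest mean, and 11434 genes entered the list tests. Stat3 and RT1-Ba had a further probe set called in the opposite direction and are not described.

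A linear model with 1 mean per group was fitted to all 16 arrays in limma 3.58.1 under R 4.3.3, so that the groups shared 1 estimate of the spread. The contrasts were the CDAA diet against the normal diet in control rats and under hydrogen, hydrogen against control on each diet, their difference (interaction) and their average. Moderated statistics came from eBayes, p-values were adjusted by Benjamini-Hochberg over the 22634 probe sets within each contrast, and an adjusted p under 0.05 counted as a call. All adjusted p-values of genes in the text come from limma, and errors beside log2 changes are standard errors of the fit unless SD is stated. Folds are 2 to the power of the log2 difference. Where a gene lay below 3.68 on every array of 1 group only, its fold is given as "at least", with that line in place of the mean of the lower group. Tests on single values per array were exact two-sided permutation tests, adjusted within their family. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

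Before the data were examined, 35 gene lists of liver functions, stress responses, other cell types and possible contamination were fixed, with 838 genes of which 695 were measured, together with the comparisons, the tests, the rule for naming genes and the alternatives unless said otherwise. Lists were tested against all other genes with camera at a preset correlation of 0.01, again with the correlation estimated from the data, and with fry, which asks whether a list's genes move one way without comparing them with other genes. List p-values were adjusted over the 35 lists of a contrast. Members passing are counted over all genes, and where no second count is given, adjustment over the list alone gave the same one. Camera with the preset correlation called 14 lists for the diet in control rats, 18 for the diet under hydrogen, 4 for hydrogen on the normal diet, 12 for hydrogen on the CDAA diet, 8 for the interaction and 7 for the average. With the estimated correlation it called 0 in each, with smallest adjusted p of 0.42, 0.453, 0.979, 0.832, 0.906 and 0.754. Fry called 27 and 27 lists for the diet and 0 in the others, where its smallest adjusted p were 0.972, 0.15, 0.733 and 0.242. Its mixed test, which asks whether a list's genes change in either direction, called 34, 34, 0, 10, 1 and 1 lists in the order above. For the clock list, whose members go both ways, it gave an adjusted p = 1.33e-05 for hydrogen on the CDAA diet and 2.39e-05 for the average.

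Genes named in the text follow a rule. For a contrast with at least 30 calls these are the 12 highest and 12 lowest called genes whose groups do not overlap (without that condition for the average), and up to 4 called members of each list. With fewer calls, all called genes were named. Of the 5 higher and 5 lower genes of smallest p some are given as values, as are up to 2 members of a described list with none called. The rule gave 320 genes, and a gene named once may be followed through the other contrasts. Cry1 and Clec4f are list members outside the rule and were chosen after their values were seen, as were the 2 unnamed probe sets.

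The steps were tested on simulated data made from the mean levels of control rats on the normal diet and the residual spread of the fit to all groups. In each of 10 simulations 200 of 22634 probe sets were changed in the hydrogen CDAA arrays. For hydrogen against control on the CDAA diet the fit recovered 76.6% of changes of 0.5 log2, 96.3% of 1 log2 and 99.7% of 2 log2, with 4.7% false calls and 100% correct signs. Camera on 11434 genes found a shifted list in 10 of 10 simulations and called 0.2 other lists on average. The simulated noise was independent between genes and equal in all groups. These rates therefore do not cover correlated genes, structure among the samples or the larger spread of the CDAA groups.

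Replicates were compared before use. Pearson correlations between arrays of a group ran from 0.9927 to 0.9965 (control, normal diet), 0.9954 to 0.9969 (hydrogen, normal diet), 0.9893 to 0.9958 (control, CDAA diet) and 0.9867 to 0.9932 (hydrogen, CDAA diet), and no pair was a duplicate. The root mean square SD per group was 0.146, 0.117, 0.175 and 0.193 log2 in that order.

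Alternatives were no filter, a stricter filter at the median (4.35 log2), quantile normalization applied again, centring on the array median, only the 2 groups of a contrast, eBayes with trend and robust settings, array weights, the replicate number as a block, 1 probe set per gene, the mean of a gene's probe sets, a minimum fold of 1.2, a floor at the 30th percentile, and leaving out each array in turn. Added after seeing the data were a clock index as a covariate, the Gapdh 3' minus 5' difference (a measure of RNA integrity) as a covariate, list tests without control normal-diet replicate 4, and fits without both replicate 4 controls. The clock index of an array is the mean standardised level of 10 measured genes of one clock phase (Dbp, Per2 and others) minus that of 4 genes of the opposite phase (Bmal1, Npas2 and others), so it is not independent of the clock genes.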

Results

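Gene expression was measured in the livers of 16 male F344 rats, an inbred laboratory strain, with 1 Affymetrix RG-230 PM array per rat liver sample. The labels give an age of 4 weeks and 3 weeks of rearing. The rats formed 4 groups of 4. One pair of groups ate normal chow and the other pair a choline-deficient L-amino acid-defined (CDAA) diet, which produces fatty liver and later fibrosis in rats. Within each diet, 1 group drank hydrogen-rich water (0.7 mM dissolved hydrogen) and lived in air with 2% hydrogen, and the control group received dehydrogenized water and plain air. The deposited values were normalised log2 signals between 2.42 and 13.73, with array medians of 4.33 to 4.38. Replicates are separate samples per the labels, and the number of arrays limits the precision. Of 31139 probe sets on the array, 22634 were tested. The comparisons address what the diet changed in control and in hydrogen-treated rats, what hydrogen changed on each diet, and whether the effect of hydrogen differed between the diets.

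In control rats the CDAA diet changed single genes of lipid handling, tissue remodelling, stress and amino acid metabolism by large folds. Fabp4, a fatty acid carrier of adipocytes and macrophages, was 17.5-fold higher (log2 4.13 ± 0.444, standard error, n = 4 per group, adjusted p = 9.4e-06), and Mmp12, the macrophage elastase, was 12.0-fold higher (4.76 to 8.34 log2, adjusted p = 2.85e-06). Stac3 was 51.5-fold lower (log2 −5.69 ± 0.71, adjusted p = 2.87e-05) and Cyp3a9, a steroid-metabolising cytochrome, was 17.4-fold lower (adjusted p = 3.9e-06). On each of these 4 genes every CDAA array lay on one side of every normal-diet array. Among the other largest increases were Serpina7, which encodes thyroxine-binding globulin (12.3-fold, standard error 0.488), Enc1 (12.0-fold), the growth regulator Myc (11.5-fold), the gastrointestinal glutathione peroxidase Gpx2 (11.4-fold), the sulphotransferase Sult2a6 (11.4-fold), and Phgdh, which catalyses the initial step of serine synthesis (10.7-fold). They were followed by the stress regulator Nupr1 (9.50-fold), the acyl-CoA thioesterase Acot1 (9.30-fold), the pantetheinase Vnn1 (7.35-fold) and the asparagine synthetase Asns (7.32-fold). Their adjusted p-values lay between 5.31e-06 for Vnn1 and 2.46e-04 for Myc. Among the largest decreases were the odorant-binding Obp3 (38.4-fold lower), the methyltransferase Inmt (18.1-fold), the ornithine aminotransferase Oat (9.90-fold), and the urinary protein gene Mup5 (8.06-fold). Smaller decreases were those of Sez6 (6.26-fold), the male-specific cytochrome Cyp2c11 (5.57-fold, standard error 0.666, adjusted p = 0.00841), the complement component C6 (5.15-fold), Nrep (4.87-fold) and the serine dehydratase Sds (4.82-fold). The Obp3 probe set can also bind related family members. Zfp37 lay below the detection line on every CDAA array and was at least 3.50-fold lower (adjusted p = 1.14e-06). Fgf21, a hepatokine of the stress and fasting responses, rose 16.5-fold (standard error 0.881, adjusted p = 0.0021).

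Among the gene lists fixed in advance, camera called 6 higher on the CDAA diet in control rats. Counts of list members are to be read against all 11434 genes, of which 3119 rose and 1520 fell in this comparison. Of 36 measured collagen and extracellular matrix genes, 19 rose and 2 fell (20 and 3 adjusted over the list alone), with a median log2 change of 0.44. Timp1, an inhibitor of matrix metalloproteinases, rose 4.21-fold (standard error 0.29), the proteoglycan Dcn 3.11-fold and the fibrillar collagen gene Col5a2 2.13-fold. Of 24 inflammatory genes 11 rose and none fell (12 adjusted over the list alone, median 0.34), including the chemokine genes Cxcl1 (4.04-fold), Ccl2 (3.33-fold) and Cxcl16 (2.66-fold) and the adhesion molecule gene Vcam1 (2.58-fold). Bile duct, progenitor and preneoplastic markers had the same direction: 13 of 20 rose on either adjustment (median 0.60), with Anxa5 at 3.80-fold, Cldn7 at 3.57-fold and Gstp1, the placental glutathione transferase of preneoplastic rat liver, at 1.63-fold. Cell cycle genes rose in 16 of 45 cases on either adjustment (median 0.49), with the proliferation marker Mki67 at 2.67-fold (standard error 0.397, adjusted p = 0.0111) and Kif20b at 1.94-fold. Of 15 immediate early genes 9 rose on either adjustment (median 0.73), among them Atf3 (9.22-fold) and Jun (3.05-fold). Of 15 mitochondrial chaperone genes 10 rose and 1 fell (11 and 1 adjusted over the list alone, median 0.25). In this test of a list against the other genes, limma's camera with its preset correlation, the lists had adjusted p = 0.0023 for the matrix, inflammatory and bile duct lists, 0.00619 for cell cycle, 0.0164 for immediate early and 0.0214 for mitochondrial chaperones. None of these calls held with an estimated correlation, which gave an adjusted p = 0.5 for the inflammatory and bile duct lists, adjusted p = 0.509 for matrix and chaperones, adjusted p = 0.552 for immediate early and adjusted p = 0.671 for cell cycle.

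Camera called 8 lists lower, of which 6 held functions of the hepatocyte and 2 markers of lymphocytes and blood cells. Growth hormone-dependent genes, not all of them of male pattern, fell in 9 of 18 cases on either adjustment and none rose (median log2 change −0.69, camera adjusted p = 2.71e-06). Igfals, the carrier subunit of the insulin-like growth factor complex, was 3.16-fold lower (standard error 0.185). Of 29 genes of amino acid and urea cycle catabolism 18 fell and 2 rose on either adjustment (median −0.42, adjusted p = 1.32e-07), including the proline dehydrogenase Prodh (2.53-fold lower) and Ddc (2.45-fold lower, adjusted p = 6e-07). Bile acid synthesis and transport genes fell in 9 and rose in 2 of 19 cases (10 and 2 adjusted over the list alone, median −0.48, adjusted p = 3e-04), among them the sterol exporter gene Abcg5 (2.26-fold lower) and the uptake carriers Slco1a4 (2.04-fold) and Slco1b2 (1.63-fold). Of 24 cytochromes and drug-metabolising genes 10 fell and 3 rose (12 and 4 adjusted over the list alone, median −0.28, adjusted p = 0.00619). Of 26 hepatocyte identity and plasma protein genes 10 fell and 1 rose on either adjustment (median −0.12, adjusted p = 0.000382). In methionine, choline and one-carbon metabolism 12 of 29 genes fell and 6 rose on either adjustment. The glycine methyltransferase Gnmt was 2.88-fold lower and the cystathionine synthase Cbs 2.57-fold lower, while the methionine adenosyltransferase Mat2a rose 4.04-fold (standard error 0.22) and the choline kinase Chka 1.76-fold. The median of that list was −0.19 and its mean 0.041, and camera called it lower (adjusted p = 0.00584). Lymphocyte and NK cell markers fell in 5 and rose in 1 of 19 cases (4 and 0 adjusted over the list alone, median −0.093, adjusted p = 0.0159), with the granzyme Gzma 1.62-fold lower. Blood cell genes fell in 2 of 3 cases on either adjustment (median −0.59, adjusted p = 0.0403), namely Slc4a1 (1.67-fold lower) and Alas2 (log2 −0.59). With an estimated correlation the growth hormone, amino acid, bile acid, hepatocyte and cytochrome lists each had an adjusted p = 0.42, the one-carbon and blood lists an adjusted p = 0.45, and the lymphocyte list an adjusted p = 0.491.

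Other lists held changed genes without being called against the remaining genes. Macrophage and Kupffer cell markers rose in 12 and fell in 3 of 21 cases (median 0.41, adjusted p = 0.0859), with Gpnmb at 5.96-fold and Cd68 at 1.88-fold higher and the Kupffer cell lectin Clec4f lower (log2 −0.61, adjusted p = 0.00892). MHC class II antigen presentation genes rose in 6 and fell in 1 of 11 cases (8 and 1 adjusted over the list alone, median 0.40, adjusted p = 0.0618), with Cd74 at 1.65-fold. Of 24 targets of the fatty acid receptor PPARα, 8 rose and 1 fell (median 0.10, adjusted p = 0.105). In the lipid droplet list the fatty acid transporter Cd36 rose 4.85-fold. Lipoprotein lipase, Lpl, of the same list rose 6.75-fold (standard error 0.239, adjusted p = 2.75e-06) and the lipid droplet protein Cidea 3.75-fold. The antioxidant NRF2 list rose in 13 and fell in 1 of 29 cases (median 0.27, adjusted p = 0.0592), with Gsta3 at 5.75-fold. Fatty acid synthesis genes fell in 6 and rose in 2 of 19 cases (median −0.02, adjusted p = 0.0918) and cholesterol synthesis genes fell in 7 and rose in 2 of 20 (median −0.054, adjusted p = 0.0769). Without control normal-diet replicate 4 camera called the NRF2 list (adjusted p = 0.033, or adjusted p = 0.449 with an estimated correlation) and the macrophage list (adjusted p = 0.048, or adjusted p = 0.668), and the fatty acid median was 0.002.

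In total 8027 probe sets (35.5% of those tested) differed between the diets in control rats by limma with Benjamini-Hochberg adjustment, 4760 higher and 3267 lower on the CDAA diet. Of these, 341 were over 2-fold higher and 242 over 2-fold lower. The split depends on the scaling: quantile normalization applied again gave 3941 higher and 3825 lower, and centring each array on its median, which moved all differences by −0.065, gave 3686 higher and 5274 lower. The medians of the called lists kept their sign under both scalings. Leaving out 1 array moved some of the folds over 1.5 times without ending their calls. Without control normal-diet replicate 4 the folds were 21.1 for Enc1, 20.8 for Myc, 19.3 for Serpina7, 18.2 for Phgdh, 17.3 for Sult2a6, 17.3 for Atf3, 15.9 for Nupr1 and 35.1 for Fgf21. Fabp4 then lay below the detection line on the other 3 arrays of its group and was at least 18.4-fold higher (26.4-fold by the means). Without control CDAA replicate 4, Stac3 was 114.0-fold lower, Obp3 84.0-fold lower and Inmt 27.4-fold lower, and Gsta3 was 8.68-fold higher without control CDAA replicate 1. Without control CDAA replicate 2 Obp3 was 21.1-fold lower, Mup5 5.15-fold lower and Atf3 14.7-fold higher.

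**Figure D1:**
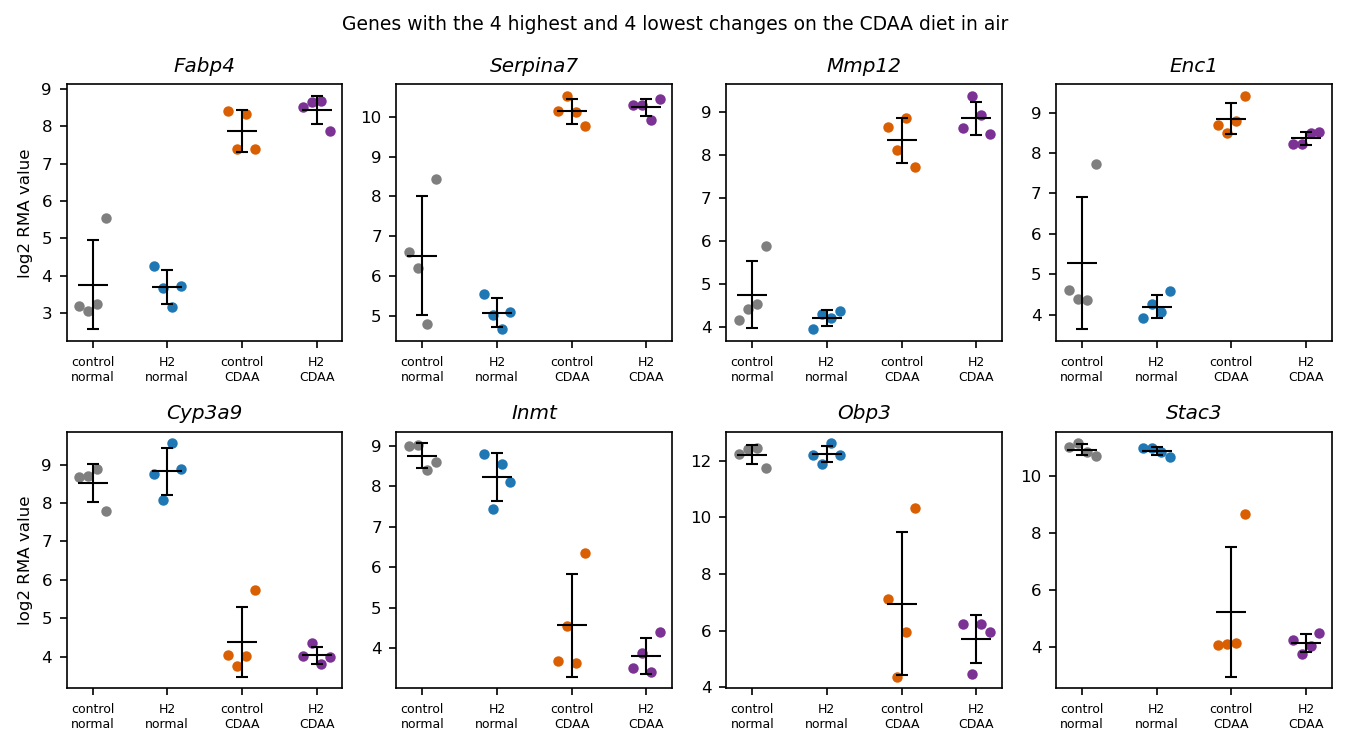
Log2 signal (vertical axes) of 8 genes on each array in the 4 groups (horizontal axes), with the group mean and SD of 4 arrays as bars. Fabp4, Serpina7, Mmp12 and Enc1 lay 12.0-fold to 17.5-fold higher and Cyp3a9, Inmt, Obp3 and Stac3 17.4-fold to 51.5-fold lower in control rats on the CDAA diet than on the normal diet.

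One array of the normal-diet control group stood between the diets. On the leading principal component, which held 66.0% of the variance, the groups had mean positions of −28.3 (control, normal diet), −33.6 (hydrogen, normal diet), 29.1 (control, CDAA diet) and 32.9 (hydrogen, CDAA diet). Control normal-diet replicate 4 lay at −13.44, against −32.28, −35.09 and −32.45 for its 3 fellow arrays. Genes that the diet raised, such as Fabp4 and Phgdh, were higher on this array than on the others of its group. Without it limma called 7858 probe sets between the diets in control rats, 7392 of them shared with the 8027.

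**Figure D2:**
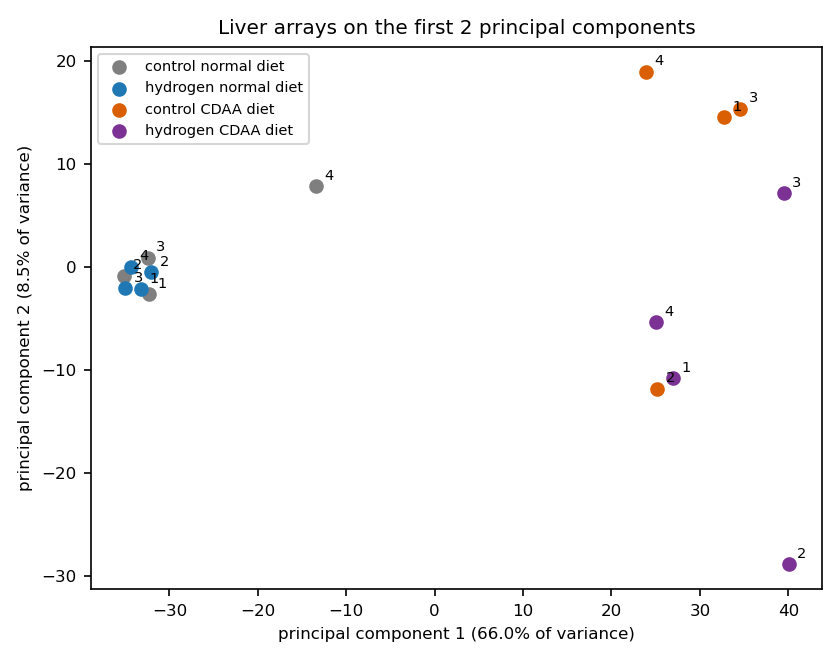
Position of the 16 arrays on the leading pair of principal components of the log2 signals, coloured by group; the horizontal axis holds 66.0% and the vertical axis 8.5% of the variance. The diets lie apart along the horizontal axis, and control normal-diet replicate 4 at −13.44 lies nearer to the CDAA arrays than the other 7 normal-diet arrays do.

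In hydrogen-treated rats the CDAA diet moved many genes of the same lists as in control rats. Serpina7 was 35.8-fold higher (log2 5.16 ± 0.488, standard error, n = 4 per group, adjusted p = 1.44e-06), Fabp4 26.6-fold, Mmp12 25.1-fold and Lpl 14.9-fold (adjusted p = 1.26e-07). Acot1, which lay below the detection line on every array of the hydrogen normal-diet group, was at least 27.4-fold higher (adjusted p = 1.78e-07). Stac3 was 106.7-fold lower (standard error 0.71), Obp3 91.6-fold, Cyp3a9 27.5-fold, Inmt 21.4-fold, Oat 16.0-fold and Cyp2c11 13.4-fold lower. For Cyp2c11 the fold was 8.61 without hydrogen CDAA replicate 2 and 22.5 without hydrogen CDAA replicate 4. Phgdh (18.4-fold), Enc1 (log2 4.17), Gpx2 (17.6-fold), Vnn1 (15.1-fold), Pbsn (12.2-fold), Sult2a6 (11.8-fold) and Myc (11.7-fold) were higher, while Mup5 (10.7-fold), the taurine transporter Slc6a6 (6.48-fold), C6 (6.44-fold) and Sez6 (5.89-fold) were lower. The triglyceride lipase gene Pnpla3 was at least 8.72-fold lower and Zfp37 at least 4.06-fold lower.

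Fatty acid synthesis genes fell in 11 and rose in 1 of 19 cases under hydrogen on either adjustment (median log2 change −0.45, camera adjusted p = 0.000147). Acly, which supplies cytosolic acetyl-CoA, was 2.56-fold lower (standard error 0.262), the elongase Elovl5 2.43-fold lower and Fasn, the fatty acid synthase, 2.35-fold lower (adjusted p = 3.92e-04). Cholesterol synthesis genes fell in 12 and rose in 3 of 20 cases on either adjustment (median −0.40, adjusted p = 0.000411), with Tm7sf2 at 3.23-fold, the sterol sensor Insig1 at 2.80-fold and Dhcr7 at 1.70-fold lower. PPARα targets rose in 12 and fell in 3 of 24 cases (median 0.36, adjusted p = 0.0331), with Acot2 at 3.64-fold. Cd36, of the lipid droplet list, rose 6.31-fold. Macrophage markers rose in 14 and fell in 1 of 21 cases (14 and 2 adjusted over the list alone, median 0.70, adjusted p = 0.00824), with Gpnmb at 9.25-fold, Lgals3 at 3.56-fold and Adgre1, which encodes F4/80, at 2.31-fold. MHC class II genes rose in 9 of 11 cases and none fell (9 and 1 adjusted over the list alone, median 0.70, adjusted p = 0.00896). Stellate cell genes rose in 9 and fell in 1 of 17 cases (median 0.26, adjusted p = 0.0414), and NRF2 targets rose in 16 and fell in 3 of 29 (median 0.33, adjusted p = 0.0122). Inflammatory genes rose in 16 and fell in 1 of 24 cases (18 and 1 adjusted over the list alone, median 0.51, adjusted p = 0.000597). Matrix genes rose in 19 and fell in 3 of 36 (19 and 4 adjusted over the list alone, median 0.44, adjusted p = 0.0122), and bile duct markers rose in 13 of 20 (median 0.80, adjusted p = 0.00357). Cell cycle genes rose in 15 of 45 (14 adjusted over the list alone, median 0.42, adjusted p = 0.0183). Growth hormone-dependent genes fell in 14 of 18 cases (16 adjusted over the list alone, median −0.95, adjusted p = 1.16e-07). Amino acid catabolism genes fell in 19 and rose in 2 of 29 (20 and 2 adjusted over the list alone, median −0.55, adjusted p = 3.08e-07). The hepatocyte list fell in 13 and rose in 1 of 26 cases (median −0.20, adjusted p = 3e-04) and the one-carbon list fell in 14 and rose in 4 of 29 (median −0.20, adjusted p = 0.0026). The bile acid list fell in 11 and rose in 3 of 19 (median −0.46, adjusted p = 0.00277) and the cytochromes fell in 8 and rose in 4 of 24 (median −0.18, adjusted p = 0.018). Lymphocyte markers fell in 3 and rose in 1 of 19 cases (median −0.092, adjusted p = 0.0343). Of all 11434 genes 3673 rose and 1983 fell under hydrogen. The 15 of 45 cell cycle genes that rose and the 3 of 19 lymphocyte markers that fell lie near those shares. None of the 18 list calls held with an estimated correlation: the adjusted p was 0.528 for stellate cell genes, adjusted p = 0.55 for PPARα targets, matrix and macrophage genes, adjusted p = 0.746 for cell cycle, and adjusted p = 0.453 for the other 13. Without control normal-diet replicate 4 camera also called immediate early genes (adjusted p = 0.0437, or adjusted p = 0.59 with an estimated correlation).

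By limma 10149 probe sets (44.8%) differed between the diets under hydrogen, 5778 higher and 4371 lower, with 558 over 2-fold higher and 279 over 2-fold lower. Quantile normalization applied again gave 4560 higher and 5006 lower, and centring on the array median, which moved the differences by −0.10, gave 4220 and 8167. The Gapdh 3' minus 5' difference, a measure of RNA integrity, was 0.185 higher on the CDAA diet in these groups, and with it as a covariate 6867 probe sets were called. Both diet comparisons use different arrays. They shared 3981 higher and 2300 lower probe sets, against 1215.1 and 630.9 for independent lists, 9 were called in opposite directions, and the correlation of their log2 changes across probe sets, which are not independent replicates, was 0.898. Of the 6281 probe sets called in the same direction, 61.6% had the larger change under hydrogen (medians 0.45 in control rats and 0.49 under hydrogen), but this share was 52.2% without control normal-diet replicate 4 and 50.0% without both replicate 4 controls, so a larger diet effect under hydrogen rests on those arrays. For the lists called by camera in only 1 of these comparisons, the interaction of diet and hydrogen had adjusted p = 5.19e-07 for fatty acid synthesis, 5.95e-05 for cholesterol synthesis, 0.00389 for macrophage markers, 0.0197 for MHC class II and 0.049 for PPARα targets. With an estimated correlation each had an adjusted p = 0.906, and without control normal-diet replicate 4 those of macrophage markers (0.0532), MHC class II (0.0532) and PPARα targets (0.0607) did not pass. The interaction did not pass for NRF2 (0.218), stellate cell (0.159), mitochondrial chaperone (0.194), immediate early (0.398) or blood cell genes (0.399).

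On the normal diet hydrogen changed few single genes. Wasf1, a regulator of actin branching, rose from 5.48 to 6.31 log2 (1.78-fold, standard error 0.109, n = 4 per group, adjusted p = 0.0235). Probe set 1379888_PM_at, which has no gene name here, fell from 5.78 to 4.68 (2.14-fold lower, standard error 0.152, adjusted p = 0.0235). These were the only calls among 22634 probe sets by limma, of which 1692 had an unadjusted p under 0.05. Neither call held without control normal-diet replicate 4, where 0 were made and Wasf1 had an adjusted p = 0.0681. The count was also 0 without control normal-diet replicate 1 or 2 or hydrogen normal-diet replicate 3 or 4, 1 without hydrogen normal-diet replicate 2, 10 without control normal-diet replicate 3 and 11 without hydrogen normal-diet replicate 1. Genes with the next smallest p-values did not pass: Btbd2 had a log2 difference of 0.46 (adjusted p = 0.0619), Stambpl1 −0.72 (0.0625), Lgalsl −0.89 (0.101) and Cmklr1, the chemerin receptor, 0.32 (0.112).

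Camera called 4 of the 35 lists between hydrogen and control rats on the normal diet. Cholesterol synthesis (median log2 difference 0.21, adjusted p = 1.16e-06), fatty acid synthesis (0.16, adjusted p = 0.00576) and respiratory chain genes (0.036, adjusted p = 0.0432) were higher, and cell cycle genes (−0.20, adjusted p = 1.22e-06) were lower with hydrogen. No member of these or the other lists passed over all genes. Adjusted over the list alone, Dbp (log2 1.28 ± 0.301, adjusted p over all genes = 0.224), Nr0b2 (1.19), Egr1 (−1.06) and S100a9 (−0.44) passed in the clock, bile acid, immediate early and neutrophil lists. The named members of the called lists were Insig1 at 0.46 (adjusted p = 0.726), Mvd at 0.41 (adjusted p = 0.503), Pnpla3 at 1.23 (adjusted p = 0.638), Mki67 at −0.99 (adjusted p = 0.604) and Rrm2 at −1.05 (adjusted p = 0.596). With an estimated correlation each of the 4 lists had an adjusted p = 0.979. Without control normal-diet replicate 4 camera called 5 more: heat shock (adjusted p = 0.00743), NRF2 (0.0262), matrix (0.0276), interferon (0.0262) and endothelial genes (0.0152). With an estimated correlation each of these had an adjusted p = 0.914.

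On the CDAA diet genes of the circadian clock differed between hydrogen and control rats, and Dbp had the largest difference of the genes called. This clock output transcription factor rose 5.41-fold (5.71 to 8.14 log2, standard error 0.301, n = 4 per group, adjusted p = 0.00183), Per3 2.65-fold (adjusted p = 0.00937), Per2 2.30-fold (adjusted p = 0.0278) and Tef 1.87-fold (adjusted p = 0.0286). Bmal1, the activator of the opposite phase, was 2.44-fold lower (5.29 to 4.00 log2, standard error 0.167, adjusted p = 0.00223). Npas2 was 2.19-fold lower (adjusted p = 0.05, under the threshold before rounding), Nfil3 1.94-fold lower (adjusted p = 0.05, likewise) and Cry1 fell by 0.53 log2 (adjusted p = 0.00515). Of 16 measured clock genes 4 rose and 4 fell (11 and 4 adjusted over the list alone), and camera called the list higher (median 0.52, adjusted p = 0.00224; adjusted p = 0.832 with an estimated correlation). For Dbp, Per2, Per3, Tef, Bmal1, Nfil3 and Cry1 the hydrogen and control arrays on this diet did not overlap, whereas those of Npas2 did. The calls of Dbp, Per3, Bmal1 and Cry1 held when any 1 of the 16 arrays was left out, whereas those of Per2, Tef, Npas2 and Nfil3 ended without control CDAA replicate 4 (adjusted p = 0.114, 0.123, 0.189 and 0.143). Left out 1 at a time, 3 of the 16 arrays ended the call of Per2, 5 that of Tef, 13 that of Npas2 and 15 that of Nfil3. The call of Tef also ended with the mean of a gene's probe sets (adjusted p = 0.124), and that of Nfil3 without the filter on dim probe sets (adjusted p = 0.0713) and after quantile normalization again (adjusted p = 0.0543). A clock index of each array, the mean standardised level of 10 genes of one clock phase minus that of 4 genes of the opposite phase, averaged −1.09 in control and 0.316 in hydrogen rats on the normal diet, and −1.46 and 2.23 on the CDAA diet. The difference on the normal diet, 1.40, and on the CDAA diet, 3.69, each had an exact permutation p of 0.0286, the smallest that 4 against 4 arrays allow, or 0.0858 after adjustment. The index was added after the clock result was seen and holds genes called above. On the CDAA diet its p is therefore no independent evidence.

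**Figure D3:**
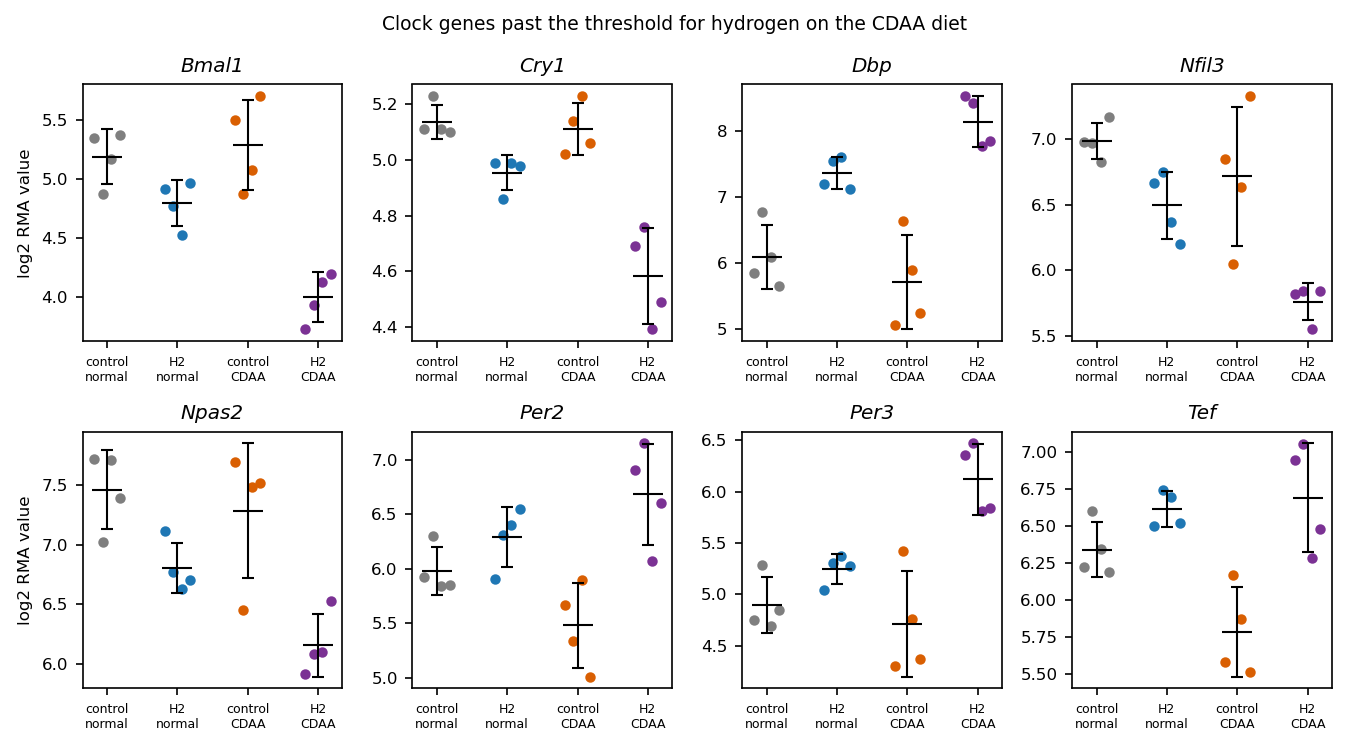
Log2 signal (vertical axes) of the clock genes Bmal1, Cry1, Dbp, Nfil3, Npas2, Per2, Per3 and Tef on each array of the 4 groups (horizontal axes), with the mean and SD of 4 arrays as bars. On the CDAA diet Dbp averaged 5.71 in control and 8.14 in hydrogen rats, and Bmal1 5.29 and 4.00.

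Outside the clock list, Hsd17b2, which inactivates oestradiol and testosterone, was higher with hydrogen on the CDAA diet (2.73-fold, standard error 0.177, adjusted p = 0.00183). Also higher were the lipid-oxidation genes Acot1 (3.68-fold, adjusted p = 0.0441), the carnitine palmitoyltransferase Cpt1b (1.98-fold, adjusted p = 0.03) and the peroxisomal Crot (1.45-fold, adjusted p = 0.0132). Smaller increases were those of the cold-induced Cirbp (1.53-fold), Oplah (1.47-fold), Fzd8 (1.46-fold), Rusc2 (1.43-fold), the bile acid enzyme Hsd3b7 (1.36-fold) and the mitochondrial sirtuin Sirt4 (1.28-fold). Among the decreases were Rprm (2.70-fold lower, standard error 0.182, adjusted p = 0.00223), Fasn (2.32-fold, adjusted p = 0.03), Lgalsl (2.19-fold), Insig2, a brake on sterol synthesis (2.15-fold) and the choline kinase Chka (2.10-fold). Others were Osgin1 (1.95-fold), the nuclear receptor Rora (1.89-fold), Tmcc3 (1.85-fold), Dipk2a (1.76-fold), Sesn2 (1.63-fold) and Pnrc1 (1.61-fold). The calls of Hsd17b2, Crot, Rprm, Lgalsl, Insig2, Chka, Tmcc3 and Dipk2a held when any 1 of the 16 arrays was left out. Without control CDAA replicate 4 the adjusted p was 0.166 for Acot1, 0.137 for Cirbp, 0.123 for Cpt1b, 0.119 for Fasn, 0.114 for Rusc2, 0.195 for Rora, 0.18 for Sesn2 and 0.10 for Pnrc1. Without control CDAA replicate 3 it was 0.107 for Hsd3b7, 0.0982 for Oplah, 0.0726 for Osgin1 and 0.144 for Sirt4, and without hydrogen CDAA replicate 1 it was 0.121 for Fzd8. Left out 1 at a time, 14 of the 16 arrays ended the call of Sesn2 and 13 that of Rora. For Acot1, Fzd8 and Sirt4 12 arrays each did so, for Cirbp 10 and for Hsd3b7 6. For Cpt1b, Fasn and Rusc2 the count was 5 each, and for Oplah, Osgin1 and Pnrc1 4 each. Without the filter on dim probe sets the adjusted p was 0.0588 for Acot1, 0.0707 for Rora and 0.0606 for Sesn2, and with the mean of a gene's probe sets 0.066 for Cirbp and 0.0847 for Sesn2. The metallothionein genes Mt1 (log2 1.13, adjusted p = 0.0737) and Mt2A (1.69, adjusted p = 0.205), Fgf21 (−2.80, adjusted p = 0.227) and Gadd45a (−1.16, adjusted p = 0.171) did not pass.

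Camera called 12 of the 35 lists between hydrogen and control rats on the CDAA diet. Besides the clock, PPARα targets were higher (median log2 difference 0.19, adjusted p = 0.000448), as were NRF2 targets (0.12, adjusted p = 0.00224) and macrophage markers (0.20, adjusted p = 0.00636). Bile acid genes (0.12, adjusted p = 0.0408) and stellate cell genes (0.12, adjusted p = 0.0429) were higher too. Lower lists were the ER and integrated stress response (−0.16, adjusted p = 2.48e-06), cell cycle (−0.30, adjusted p = 3.02e-06) and fatty acid synthesis (−0.21, adjusted p = 0.000127). So were immediate early (−0.27, adjusted p = 0.00224), respiratory chain (−0.043, adjusted p = 0.00279) and growth hormone-dependent genes (−0.26, adjusted p = 0.00636). Few members passed singly, and of all 11434 genes only 22 rose and 21 fell. Over all genes 1 of 24 PPARα targets (Acot1), 0 of 29 NRF2 targets, 1 of 19 bile acid genes (Hsd3b7), 1 of 24 stress genes (Sesn2) and 1 of 19 fatty acid genes (Fasn) passed. Adjusted over the list alone, 10 PPARα targets rose and 2 fell, 7 NRF2 targets, 2 bile acid genes and 1 stellate cell gene rose, and 2 stress and 2 fatty acid genes fell. In the macrophage, cell cycle, immediate early, respiratory chain and growth hormone lists 0 passed on either adjustment. None of the list calls held with an estimated correlation: the PPARα, NRF2, fatty acid and stress lists had an adjusted p = 0.832, and the macrophage, bile acid, stellate, cell cycle, immediate early, respiratory chain and growth hormone lists an adjusted p = 0.868. In all, limma called 71 probe sets on the CDAA diet, 40 higher and 31 lower with hydrogen, of which 13 changed over 2-fold. The count was 54 without control normal-diet replicate 4 and 18 without both replicate 4 controls. It ranged from 21 without control CDAA replicate 4 to 346 without control CDAA replicate 2, with 44 without control CDAA replicate 1, 27 without control CDAA replicate 3, 33 without hydrogen CDAA replicate 1 and 135 without hydrogen CDAA replicate 4. A fit on the 8 CDAA arrays alone called 2. Of 35 splits of these arrays 3, the real one included, gave at least 71 calls, so chance is not excluded for this count.

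Whether hydrogen moved genes against or along with the diet was described by the correlation of its effect on the CDAA diet with the effect of the diet in control rats. Over the 22634 probe sets, which are not independent replicates, it was −0.039. Both effects use the control CDAA arrays, and simulated unchanged groups sharing those arrays gave −0.501 (SD 0.013). That simulation held no diet effect, whereas the real diet effect widens the spread of one side and draws the correlation towards zero. The value of −0.501 is therefore no yardstick for the observed one. With the control CDAA arrays split between the effects, so that none was shared, the correlation averaged 0.065 over the splits (−0.054 to 0.224). The covariance was −0.00244, against −0.00646 in the simulation, a difference of 0.00402. With no array shared it averaged 0.0052 over the splits, with values of either sign (−0.0039 to 0.0175), so neither direction is shown. Leaving out control CDAA replicate 2 gave a correlation of −0.187. Single genes went either way: Acot1 and Cpt1b rose with the diet in control rats and rose further with hydrogen, whereas Chka rose 1.76-fold with the diet and was 2.10-fold lower with hydrogen on it.

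The test of whether hydrogen acted differently on the 2 diets called 1 single probe set, 1390117_PM_at, which has no gene name here. It averaged 8.28 and 8.25 log2 in control and hydrogen rats on the normal diet, and 8.04 and 7.33 on the CDAA diet (interaction −0.68 ± 0.091, adjusted p = 0.0333). None of the genes that hydrogen changed on the CDAA diet alone passed this test. The interaction was 1.16 for Dbp (adjusted p = 0.464), −0.90 for Bmal1 (0.296), 0.98 for Hsd17b2 (0.288), and −1.56 for Fasn (0.179). It was 1.21 for Cpt1b (0.179), 2.07 for Acot1 (0.288), −0.94 for Insig2 (0.205) and −0.87 for Chka (0.233). Of the lists, camera called 8 of 35. Relative to the normal diet, hydrogen on the CDAA diet lowered fatty acid synthesis (median interaction −0.32, adjusted p = 5.19e-07), cholesterol synthesis (−0.20, adjusted p = 5.95e-05) and respiratory chain genes (−0.076, adjusted p = 9.23e-05). It also lowered stress response (−0.13, adjusted p = 0.000628) and growth hormone-dependent genes (−0.25, adjusted p = 0.0128). It raised macrophage markers (0.28, adjusted p = 0.00389), MHC class II genes (0.27, adjusted p = 0.0197) and PPARα targets (0.15, adjusted p = 0.049). No member passed over all genes. Adjusted over the list alone, 2 fatty acid synthesis genes, 3 stress response genes and 2 PPARα targets (1 each way) passed. Of the lists that camera did not call, the clock list had the most, with 6 positive and 2 negative interactions, followed by acute phase and glucocorticoid genes with 2 and 1 each. Each of the 8 called lists had an adjusted p = 0.906 with an estimated correlation. Without control normal-diet replicate 4 no single probe set was called (1 of 22634 with it, 2066 at an unadjusted p under 0.05), and the adjusted p was 0.0607 for PPARα targets, 0.0532 for macrophage markers, 0.0532 for MHC class II and 0.0607 for growth hormone-dependent genes, while immediate early genes were called (adjusted p = 0.0227, or adjusted p = 0.911 with an estimated correlation). The count of single probe sets was 21 without control CDAA replicate 2, 3 without control normal-diet replicate 3, 2 without hydrogen CDAA replicate 3, 1 without control CDAA replicate 1 and 0 without any other single array. Across probe sets the hydrogen effects on the 2 diets had a correlation of 0.066, and 2804 of 4900 relabellings of the arrays within diets gave one as large (exact permutation p = 0.572).

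Averaged over both diets, hydrogen changed 37 probe sets by limma, 8 higher and 29 lower. Dbp rose 3.62-fold (log2 1.86 ± 0.213, standard error, 8 arrays per arm, adjusted p = 0.00101), Hsd17b2 1.94-fold (adjusted p = 0.00281) and Per3 1.84-fold (adjusted p = 0.0301). Rprm was 2.12-fold lower (adjusted p = 0.00127), Lgalsl 2.01-fold lower (adjusted p = 0.00101), Bmal1 1.79-fold lower (adjusted p = 0.00606) and Npas2 1.86-fold lower (adjusted p = 0.0379). Tmcc3 fell by 0.62 log2 (adjusted p = 0.00101) and the tight junction gene Cldn1 also by 0.62 (adjusted p = 0.0411). Without control normal-diet replicate 1 the adjusted p was 0.0919 for Per3, 0.108 for Npas2 and 0.114 for Cldn1. Left out 1 at a time, 10 of the 16 arrays ended the call of Per3, 11 that of Npas2 and 11 that of Cldn1. Of the 82 genes named for the average, 5 lost their call without the filter on dim probe sets. With the mean of a gene's probe sets 3 did. Of 16 clock genes 2 rose and 4 fell (11 and 4 adjusted over the list alone, camera adjusted p = 0.00139, median 0.39). Camera also called PPARα targets (median 0.12, adjusted p = 0.000917), NRF2 targets (0.085, adjusted p = 0.00103) and bile acid genes (0.10, adjusted p = 0.00242) higher. Called lower were cell cycle (−0.22, adjusted p = 4.03e-11), stress response (−0.11, adjusted p = 0.000105) and immediate early genes (−0.17, adjusted p = 0.000626). In the PPARα, NRF2 and cell cycle lists 0 members passed on either adjustment, and adjusted over the list alone 2 bile acid genes rose and 2 stress and 3 immediate early genes fell. With an estimated correlation immediate early genes had an adjusted p = 0.828 and the other 6 lists an adjusted p = 0.754. Limma called 18 probe sets without control normal-diet replicate 4, 17 of them among the 37, and camera then also called endothelial (adjusted p = 0.00541) and stellate cell genes (adjusted p = 0.0493), each with an adjusted p = 0.796 at the estimated correlation. Other counts were 147 without control CDAA replicate 2, 69 without hydrogen CDAA replicate 3, 22 without control CDAA replicate 4, and 21 without control CDAA replicate 3, control normal-diet replicate 2 or hydrogen CDAA replicate 1. They were 18 without hydrogen normal-diet replicate 2, 17 without control normal-diet replicate 3, 15 without control normal-diet replicate 1 or hydrogen normal-diet replicate 3, and 14 without hydrogen normal-diet replicate 4.

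**Figure D4:**
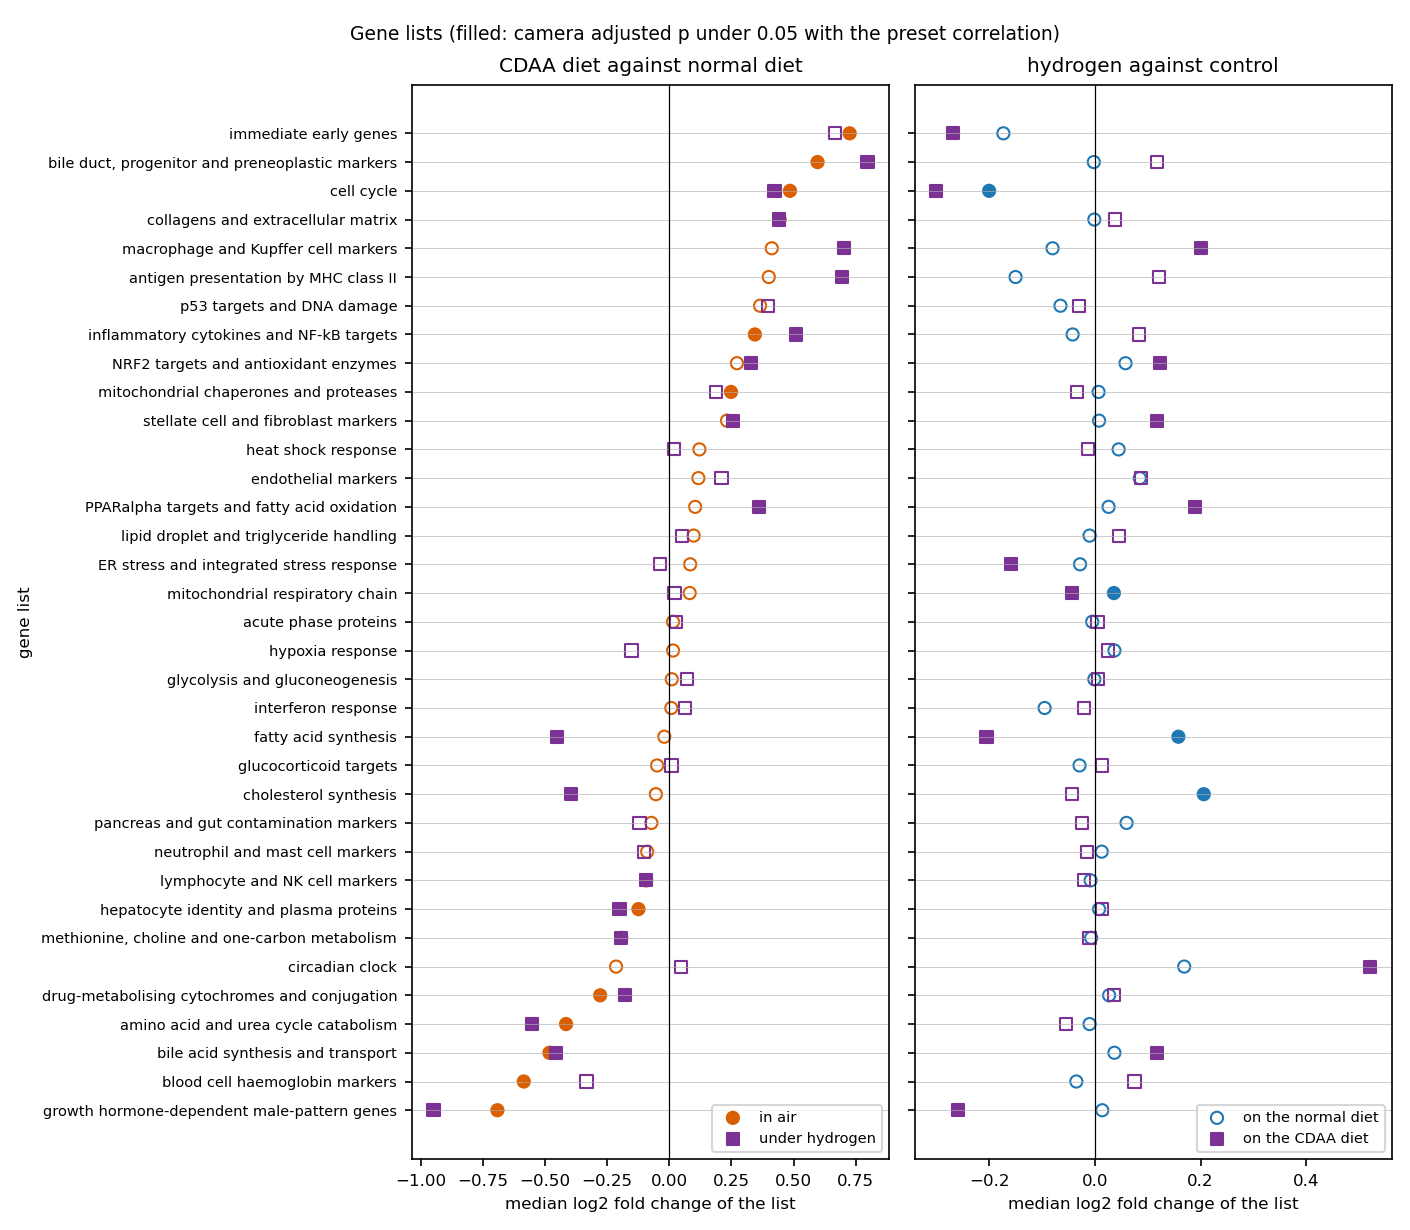
Median log2 difference (horizontal axis) of the 35 gene lists (vertical axis) for the diet in control and hydrogen rats and for hydrogen on each diet; filled points mark lists called by camera with its preset correlation. Growth hormone-dependent genes had medians of −0.69 and −0.95 for the diet, and clock genes 0.52 for hydrogen on the CDAA diet.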

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

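The 5 tests on control normal-diet replicate 4 and the clock phase and time of day tests were chosen after the result was seen; the RNA integrity and fatty acid synthesis tests were written before theirs, but the spread of the fatty acid slopes was added after.

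Control normal-diet replicate 4 lay far from the other 3 arrays of its group on the leading principal component, at −13.44, and part of its RNA may have come from a CDAA liver. On a linear scale genes higher on the CDAA diet placed it 0.27 of the way to that diet and genes lower 0.278, a difference of −0.007 (bootstrap standard error 0.0143), against 0.451 and 0.171 on the log scale; in the 7 other normal-diet arrays the genes higher gave at most 0.018, but the genes lower up to 0.225 (hydrogen normal-diet replicate 2), so the genes higher carry most of this evidence. On the CDAA diet same-numbered hydrogen and control arrays had correlations of deviations from −0.08 to 0.33 over all probe sets. A correlation between arrays of the same number therefore does not by itself single out a source. Over 7038 probe sets without a diet difference, deviations of control normal-diet replicate 4 were set against those of control CDAA arrays. Their correlation was 0.191 with control CDAA replicate 4, against at most 0.101 among 12 other pairs. From genes lower on the CDAA diet, that array in turn had a share of 0.144 of normal-diet RNA (standard error 0.008, at most 0.06 in the 7 other CDAA arrays), with Stac3 at 8.65 against 4.04 to 4.13 in its 3 fellow arrays, while genes higher gave it 0.153 but control CDAA replicate 2 0.298, so an exchange in both directions remains only a candidate explanation. A full swap of labels is excluded by the position of control normal-diet replicate 4, 0.318 of the way between the diets, with no CDAA array under 0.916. Its Gapdh 3' minus 5' difference of 0.29 lay inside the 0.20 to 0.45 of its fellows and gave no sign of degraded RNA. A single transcript on so few arrays cannot exclude degradation. A rat that responded less was not tested.

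Clock genes differed between hydrogen and control rats, and the design offers hydrogen itself as a biological explanation. With the Gapdh difference as a covariate the median absolute change of the 8 called clock genes on the CDAA diet was 1.137 against 1.166. This is a ratio of 0.97, and 5 stayed called. The Gapdh difference itself was only 0.032 higher with hydrogen on that diet (exact permutation p = 0.543), so this covariate could change little. The actin difference (−0.268 with hydrogen, exact permutation p = 0.257) was not used as a covariate, so the test cannot exclude RNA integrity as a cause. A difference in clock phase at sampling may carry other hydrogen calls too: of 63 calls outside the clock list 77.8% (95% exact binomial interval 65.5 to 87.3) had a slope on the clock index within groups of the same sign as the hydrogen change, against 58.3% of all probe sets, but without control CDAA replicate 2 the share was 60.3% (47.2 to 72.4) against 56.5%, while for the 31 such calls of the average it was 74.2% (55.4 to 88.1) with and 80.6% (62.5 to 92.5) without that array. These intervals treat the probe sets as independent although they were measured on the same arrays, so they understate the uncertainty. The arms may also have been sampled at different times of day. The clock index was higher by 1.402 with hydrogen on the normal diet as well, and because sampling times are not given, an effect of hydrogen on the clock and a sampling difference cannot be told apart.

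Fatty acid synthesis genes had opposite hydrogen differences on the 2 diets, with a median interaction of −0.322, which passed the test of the difference. The doubtful control array is excluded as the cause, since without it the interaction was −0.325, a ratio of 1.01. A linear trend with clock phase within groups would need a slope of −0.141 on the clock index, and the list's median slope was 0.02 (−0.049 to 0.041 with 1 array left out), which argues against clock phase but only just beyond the spread of the members (SD 0.159, with 9 of 19 slopes negative), so it is not firmly excluded. A dependence of the hydrogen response on the diet stays open as a hypothesis, which the estimated correlation does not bear out (adjusted p = 0.906), and feeding state at sampling was not tested.

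The hydrogen effect differed between the diets by camera's test of the interaction for 7 more lists, with medians of −0.198 for cholesterol synthesis, 0.15 for PPARα targets, −0.132 for the ER and integrated stress response, 0.28 for macrophage markers, 0.268 for MHC class II, −0.248 for growth hormone-dependent genes and −0.076 for the respiratory chain. Each had an adjusted p = 0.906 with an estimated correlation, and without control normal-diet replicate 4 the calls of PPARα targets (0.0607), macrophage markers (0.0532), MHC class II (0.0532) and growth hormone-dependent genes (0.0607) ended. The hydrogen effect also differed for the unnamed probe set 1390117_PM_at, at −0.678. Among the genes named, 82 of 1280 gene and group pairs (6.4%) had 1 array far from the other 3, where chance gives about 1 in 20.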

How the results depend on the processing

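The clock index, Gapdh and both-replicate-4 settings were chosen after the result was seen; the others were planned. The diet counts of 8027 and 10149 stayed within 1.5 times under all settings except 1 probe set per gene (4784 and 5768, fewer features tested), and with 1 array left out they ran from 6632 to 7858 and from 8841 to 10047. Hydrogen on the normal diet, with 2 calls, gave 5 with trend and robust settings, 46 with array weights, and 17 in its own 2 groups. It gave 1 with 1 probe set per gene, 0 with the clock index, 0 with Gapdh and 0 without both replicate 4 controls, and 0 to 11 with 1 array left out. Hydrogen on the CDAA diet, with 71, gave 44 with 1 probe set per gene, 2 in its own 2 groups, 0 with the clock index (2 settings that leave fewer arrays or remove much of the arm difference) and 18 without both replicate 4 controls, and 21 to 346 with 1 array left out. Of the 71, 58 were among 59 calls after quantile normalization again, 48 among 50 with Gapdh and 16 among 18 without both replicate 4 controls, and all 71 had the same sign in every setting compared except the clock index, where 64 did. The interaction, with 1, gave 3 with array weights and 0 with 1 probe set per gene, the clock index, Gapdh or without both replicate 4 controls, and 0 to 21 with 1 array left out. The average, with 37, gave 67 with array weights, 23 with 1 probe set per gene, 0 with the clock index, 16 with Gapdh and 17 without both replicate 4 controls, and 14 to 147 with 1 array left out. The correlation of hydrogen and diet effects was 0.065 with the control CDAA arrays divided so that the effects share none, and −0.187 to 0.052 with 1 array left out. Apart from these constructions the cause was not tested. For the diet in control rats, camera lost 2 list calls with the mean of a gene's probe sets and gained 6 without the filter on dim probe sets. In the other comparisons each of these settings changed at most 1 list call. Over all results and settings 4092 kept their side, 201 lost and 75 gained a call and 68 values moved. Limma gave 1692 (normal diet) and 2066 (interaction) probe sets at an unadjusted p under 0.05 in place of those small counts. With the replicate number as a block the calls were 1 for hydrogen on the normal diet, 82 on the CDAA diet (55 shared) and 0 for the interaction. Among named genes the block ended the call of Wasf1 for hydrogen on the normal diet and 1 call of the diet in control rats. It also ended 5 hydrogen calls on the CDAA diet, where it added 2, and 5 of the average. Among list calls it ended 2 for hydrogen on the CDAA diet. It ended 1 each for hydrogen on the normal diet, the interaction and the diet under hydrogen. Same-numbered arrays had correlations of deviations from −0.08 to 0.33, and 2, 6, 5 and 6 of 8 arrays in the 4 comparisons matched best with their own number. This is a hint from the data, not the design, in which the numbers only name separate rats. Signals near the background line limit the folds of dim genes, which are given as lower bounds only where every array of 1 group lies below it.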

Other observations

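The clock list slopes on the clock index were computed after the result was seen; the lists, splits and their tests were planned.

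Several lists not yet described held changed genes on the CDAA diet in control rats although camera did not call them. Of 15 measured p53 targets 8 rose and 1 fell (10 and 1 adjusted over the list alone), with a median log2 change of 0.37 (adjusted p = 0.0592), and Gadd45a, a DNA damage-inducible growth arrest gene, rose 3.05-fold. Stellate cell genes rose in 7 of 17 cases and none fell (median 0.23, adjusted p = 0.0769, or 0.048 and called without control normal-diet replicate 4, where the estimated correlation gave 0.449), and endothelial markers rose in 4 of 13 (3 adjusted over the list alone, median 0.12, adjusted p = 0.115), among them Vwf at 2.17-fold. Of 21 lipid droplet genes 9 rose and 3 fell (median 0.098, adjusted p = 0.272), of 38 respiratory chain genes 13 rose and 1 fell (14 and 1 adjusted over the list alone, median 0.082, adjusted p = 0.105), and of 20 heat shock genes 7 rose and 3 fell (median 0.12, adjusted p = 0.468). The ER and integrated stress response list rose in 9 and fell in 2 of 24 cases (median 0.084, adjusted p = 0.616), with Trib3 5.42-fold higher, a fold that was 8.63 without control normal-diet replicate 4. Clock genes fell in 3 and rose in 1 of 16 cases (2 and 1 adjusted over the list alone, median −0.21, adjusted p = 0.0592), with Hlf 3.51-fold lower. Of all 11434 genes 3119 rose and 1520 fell in this comparison, a larger share than that of the clock genes called.

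Acute phase proteins went both ways in control rats, with 5 of 25 higher and 4 lower (median 0.015, adjusted p = 0.866): the lipopolysaccharide-binding protein Lbp rose 3.41-fold and A2m, the acute phase macroglobulin of the rat, 4.49-fold, while Crp was 2.15-fold lower. Interferon response genes rose in 4 and fell in 4 of 29 cases (median 0.008, adjusted p = 0.46), and glycolysis and gluconeogenesis genes rose in 7 and fell in 6 of 18 (7 and 7 adjusted over the list alone, median 0.010, adjusted p = 0.801). Hypoxia genes rose in 3 and fell in 1 of 13 cases (median 0.015, adjusted p = 0.898). Centring on the array median turned these medians to −0.05 for acute phase, −0.058 for interferon, −0.055 for glycolysis and −0.05 for hypoxia, quantile normalization again turned hypoxia to −0.005, and camera's direction for these 4 lists was lower while their medians and means were above 0. Glucocorticoid targets rose in 3 of 12 cases (median −0.049, mean 0.298, adjusted p = 0.866), neutrophil and mast cell markers fell in 2 of 8 (1 adjusted over the list alone, median −0.089, adjusted p = 0.115), and markers of pancreas and gut tissue rose in 1 of 9 (median −0.072, mean 0.158, adjusted p = 0.307). The acute phase, interferon and hypoxia lists held a smaller share of called genes than all 11434 genes, of which 3119 rose and 1520 fell.

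Within groups, arrays with a higher clock index had lower cell cycle genes (median slope −0.194 log2 per unit, camera adjusted p = 7.82e-17), growth hormone-dependent genes (−0.163, adjusted p = 1.75e-04) and immediate early genes (−0.194, adjusted p = 5.42e-04). With an estimated correlation the adjusted p was 0.66, 0.66 and 0.763. These lists were also lower with hydrogen on the CDAA diet, so a shared clock phase may contribute to those list differences. Other lists went against this: respiratory chain genes were higher with the clock index (0.03, adjusted p = 0.00793) but lower with hydrogen, and stellate cell genes were lower with it (−0.041, adjusted p = 0.0496) but higher with hydrogen (adjusted p = 0.79 for both with an estimated correlation). The clock index varied most within the control CDAA group (SD 1.018, against 0.435 to 0.509 in the other groups). There replicate 2 had −0.057 and its fellows −2.221 to −1.362. That array may weigh heavily on these list slopes, which are not given without it. No call for hydrogen on the CDAA diet was left with the clock index as a covariate (0 against 71), a setting that also removes part of any hydrogen effect on the clock itself.

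Other splits of the same arrays gauge whether a chance division of the arrays gives as many calls, with the real split counted among them. For the diet in control rats only the real split, 1 of 35, gave as many calls as 8027 (highest other 862). Under hydrogen it was also only the real split (10149, highest other 1). A share of 1 in 35 is the smallest that 4 against 4 arrays allow and was not adjusted over the comparisons. Chance is therefore unlikely for both counts but not firmly excluded. For hydrogen on the normal diet 2 of 35 splits gave at least the real 2 calls (highest other 7), and on the CDAA diet 3 of 35 gave at least 71 (highest other 1246), so chance is not excluded for either count. The split with 1246 sets control CDAA replicates 1, 3 and 4 with hydrogen CDAA replicate 3 against the rest, and points to a structure of these samples that only partly follows the arms: control CDAA replicate 2 lay at −11.83 on the second principal component, with its fellows at 14.56 to 19.01, and its clock index was −0.057. For the interaction 12 of 100 relabellings within diets gave at least the real 1 call (highest other 303), so chance is not excluded. For the average 4 of 100 gave at least 37 (highest other 173), a share under 0.05. Apart from the real one these are a random draw of the possible relabellings, so chance is not firmly excluded. The highest other count again points to sample structure.

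The Gapdh 3' minus 5' difference averaged 0.308, 0.19, 0.342 and 0.375 in control and hydrogen rats on the normal diet and control and hydrogen rats on the CDAA diet. It was higher by 0.185 on the CDAA diet under hydrogen (exact permutation p = 0.0286, adjusted p = 0.0858). With it as a covariate 6867 probe sets were called in that comparison, against 10149. The actin difference averaged 3.03, 2.90, 3.39 and 3.12, and was higher by 0.358 on the CDAA diet in control rats (exact permutation p = 0.0571, adjusted p = 0.114).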
